A study of Mus musculus with 2 samples.

How the data were processed

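The data were RNA-seq read counts per gene from 2 libraries of RAW264.7 mouse macrophages, 1 per group. Per the labels, total RNA was extracted with TRIzol and libraries were made with a standard Illumina protocol. The authors deposited a single table of counts for both libraries, with whole numbers per gene symbol that were not normalised, and per the file headers it has the layout that featureCounts writes. Per the submitters' processing notes, the tools were fastp 0.23.4, STAR 2.5.3a and featureCounts without a version, and the build was GRCh38. That build is human, whereas the gene symbols are mouse, so the named build cannot be that of these data. Only 1358 of 49083 symbols shared with GENCODE M21 on GRCm38 had the same start there, so no coordinate of that annotation was printed. The annotation release, the strand setting and the handling of reads with several matches are not given in the sources used here. Antisense and overlapping genes therefore cannot be told apart, and genes with over 20% of their exon length in other genes were called uncertain. The columns were matched to samples by the description in the labels, and all sample columns had a match.

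The table held 56791 genes, of which 23036 had a count. Among genes with 1 to 50 counts, 76.3% of the counts in the treated and 75.1% in the vehicle library were even numbers. In the treated library 623 genes had a count of 1 and 2423 a count of 2. Both ends of a read pair thus seem to have been counted, and intervals were also computed with counts halved, a choice made after the data were seen. A value of 1 CPM corresponded to 35.6 counts in the treated and 37.8 in the vehicle library.

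With 1 library per group there are no residual degrees of freedom, so the quasi-likelihood test of edgeR could not be fitted and no p-value was computed. Counts were scaled by effective library sizes from TMM (edgeR 4.0.16 in R 4.3.3), with factors of 0.957 for the treated and 1.05 for the vehicle library. The ratio of scaled counts was given with a 95% interval from the exact Clopper-Pearson interval of the treated share of both counts. Where a count was 0, 0.5 was added for the point value, and folds against 0 were given as bounds against 3 counts in that library. Such bounds leave out error in the count of the other library. Genes with a mean of at least 1 CPM were called measured, 12264 in all, of which 10104 were protein-coding in GENCODE M21. A gene was counted as higher or lower when its ratio was at least 2-fold with an interval that excluded 1, and within gene lists when it was at least 1.5-fold. Such intervals compare the libraries, not the conditions.

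The tests, the 25 gene lists and the rule for named genes were fixed before the data were examined. The rule took the 12 highest and 12 lowest genes by the bound nearest to 1, leaving out predicted and clone names, up to 4 members with the largest log2 ratio per list among those with at least 100 counts in total, 10 fixed markers of polarization and 3 reference genes. These came to 119 genes, of which the text describes a part, and Clec10a, Cd40, Acod1, Ccl4, Bst2, Pcna, Vegfb, Rps14, Hspa1a, H2-Aa, H2-Ab1, Ciita, Col1a1, Dcn and Pecam1, like the members named so in the report, were chosen after their values were seen. A list's median log2 ratio over measured members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins. Its interval came from 1000 draws of the counts, which were not halved. The step to lists matched also on transcript length, in 10 by 10 bins, was added after the data were seen. It used the length of the principal transcript of GENCODE M21, known for 10088 measured protein-coding genes. The length correction subtracted a running median of the log2 ratio over 50 bins of that length. List members called higher or lower after it need not be those called before it.

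The alternatives were scaling by total counts, by median of ratios (DESeq2 1.42.0) and by upper quartile, no filter, a filter at 10 CPM, protein-coding genes only, a 1.5-fold threshold, whole intervals beyond 2-fold, 1 CPM added to both values, and means or pooled counts in place of medians. The procedure was tested on simulated counts for 12271 genes with 200 genes altered. It called 34 of 34 genes made 2.5-fold higher and 32 of 34 made 2.5-fold lower, 34 of 34 made 4-fold higher and 29 of 30 made 4-fold lower, and 1 of 12073 unaltered genes. It called 0 of 34 genes made 1.5-fold higher and 0 of 34 made 1.5-fold lower, which lie below the 2-fold threshold. Intervals held the true ratio for 95.2% of the unaltered genes. The simulated counts were independent draws scaled by total counts, without read pairs counted at both ends. These rates therefore do not carry over to the real counts. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene models, splicing and variants were not analysed here. Some genes given by the rule are not reported here.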

Results

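RNA sequencing was carried out on RAW264.7 cells, a mouse monocyte and macrophage line derived from a leukaemia, to ask what a preparation named FAPD10-exos in the labels does to M2 polarization, the alternative activation state that IL-4 induces in macrophages. As the treatment protocol in the labels is read here, both cultures received 20 ng of recombinant mouse IL-4 for 24 h, and 1 of them also received 10000000 particles of FAPD10-exos over the same period. Each group held 1 library, named here the treated and the vehicle library. The treated library held 37196241 counts over 20489 genes and the vehicle library 36152743 counts over 21012 genes. Differences between the libraries therefore have no replicate check and describe these 2 libraries only. Ratios are treated over vehicle, and the ranges in parentheses after them are 95% counting intervals. These cover counting error only and take each count as an independent read. If both ends of a read pair were counted, as the even counts point to, they are too narrow. That of the gene Cish, 4.62 to 19.3, was 3.53 to 28.9 with counts halved. A count of 0 allows up to 3 counts, which is 0.0843 counts per 1000000 counts of the effective library size (CPM) in the treated and 0.0794 CPM in the vehicle library.

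Igf1, the gene of insulin-like growth factor 1, stood first among measured genes, those with a mean of at least 1 CPM, when ranked by the interval bound nearest to 1, at 49.0 against 3.49 CPM, a ratio of 14.0 (11.7 to 16.9). Cish, a feedback inhibitor of STAT signalling, was 8.92-fold higher (4.62 to 19.3) from 84 against 10 counts. Cst7, which encodes the protease inhibitor cystatin F, was 6.37-fold higher (4.04 to 10.5), and C3, the central complement component, was 4.06-fold higher (3.48 to 4.76). At the other end, Atp7a, a copper-transporting ATPase, was 8.15-fold lower in the treated library (6.34 to 10.6), at 1.94 against 15.8 CPM. Gvin1, a very large interferon-inducible GTPase, was 5.87-fold lower (5.04 to 6.88), and Fndc3b, a membrane protein with fibronectin domains, was 4.76-fold lower (4.31 to 5.28).

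The positions that follow are those of the deposited count table, whose mouse build is not given in the sources used here. Igf1 lies on chromosome 10 from 87694127 to 87772904 on the plus strand, Cish on chromosome 9 from 107173225 to 107179983, Cst7 on chromosome 2 from 150412335 to 150420864 and C3 on chromosome 17 from 57510970 to 57535136. Atp7a lies on the X chromosome from 105070882 to 105168532, Gvin1 on chromosome 7 from 105755763 to 105814533 and Fndc3b on chromosome 3 from 27470311 to 27765456. All of these are protein-coding genes counted over their exons.

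The other genes at the top of the ranking included Rnf19b, an E3 ubiquitin ligase, at 3.81-fold higher (3.45 to 4.22), and Cd74, the invariant chain of MHC class II, at 2.95-fold higher (2.82 to 3.10). Mrps24 of the mitochondrial ribosome was 3.61-fold higher (3.18 to 4.11), Chchd10, a mitochondrial intermembrane space protein, 5.31-fold (2.96 to 10.2), Pcbd2 4.01-fold (3.10 to 5.24) and Cdk20 4.70-fold (2.60 to 9.10). Snrpert was 4.19-fold higher (2.89 to 6.22), but it is a processed pseudogene, so its value is uncertain. Rn18s-rs5, a copy of ribosomal RNA sequence, took 0.482% of the treated and 0.149% of the vehicle counts and was 3.53-fold higher (3.50 to 3.56). That value is also uncertain because the copy shares reads with other ribosomal RNA loci. After correction for transcript length, Mrps24 stood at 1.22 in log2, Pcbd2 at 1.28, Chchd10 at 1.92 and Cst7 at 2.04.

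Among the lowest genes, Zfc3h1, which takes part in nuclear RNA surveillance, was 4.27-fold lower (3.997 to 4.57), Ankrd12 4.17-fold (3.92 to 4.45), Amotl2, an adaptor of the Hippo pathway, 7.40-fold (4.23 to 14.0) and Ahnak2 5.18-fold (3.88 to 7.01). Zfp871 was 4.85-fold lower (3.99 to 5.93), Prr14l 4.34-fold (3.90 to 4.84) and the homeobox gene Zfhx4 4.26-fold (3.81 to 4.77). Gvin3, at 6.31-fold lower (3.93 to 10.7), is a near copy of Gvin1, so the division of reads between the pair is uncertain. Mir5129, at 5.10-fold lower (4.27 to 6.14), spans only 78 bases, and its counts cannot be assigned to the mature microRNA. Long transcripts were lower in general, and after the length correction Zfp871 stood at -1.28 in log2, Prr14l at -1.17, Zfhx4 at -1.07, Zfc3h1 at -1.38, Ankrd12 at -1.06, Gvin1 at -1.68 and Fndc3b at -1.56, whereas Atp7a stood at -2.59, Amotl2 at -2.56 and Ahnak2 at -2.24.

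**Figure D1:**
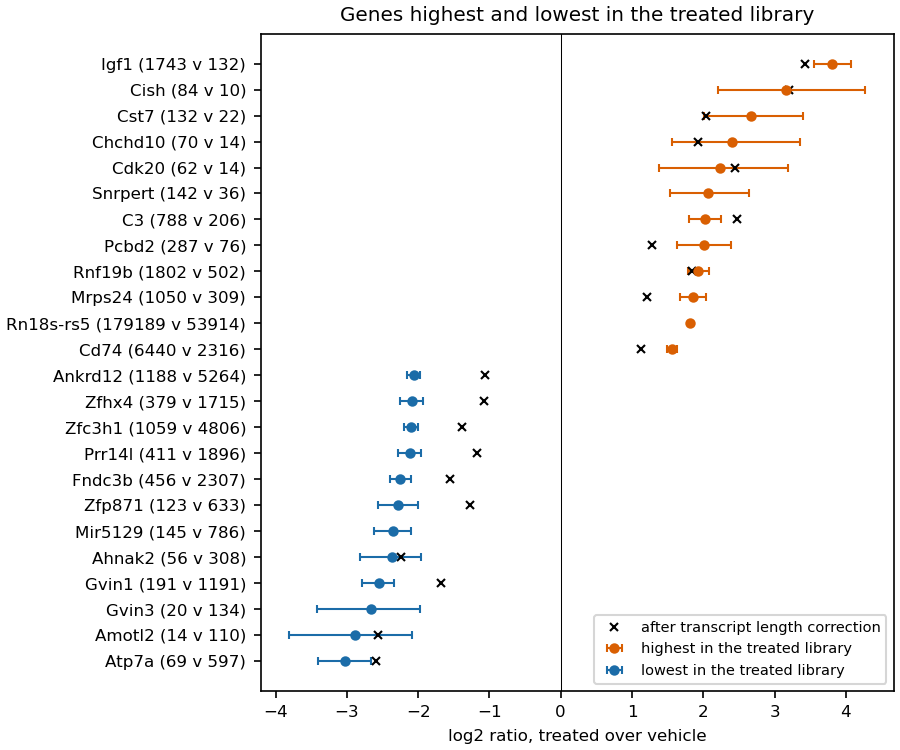
Log2 ratio (treated over vehicle, x axis) of the 12 genes highest and the 12 lowest in the treated library, with 95% counting intervals and, in parentheses, the treated and vehicle counts. Crosses give the ratio after the transcript length correction, where a principal transcript was known. Igf1 stands at 3.81 before and 3.43 after it, and Ankrd12 at -2.06 before and -1.06 after it.

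Of 12264 measured genes, 514 (4.19%) were at least 2-fold higher in the treated library with an interval above 1, and 1059 (8.64%) were at least 2-fold lower. Higher genes thus made up 32.7% of these genes, against 17.4% under scaling by total counts and 44.0% under upper-quartile scaling. At the 1.5-fold threshold used within lists, 2097 of the 12264 measured genes were higher and 2429 lower. Numbers of higher and lower list members below are to be read against that share. Scaling by total counts moved the median log2 ratio of all measured genes by -0.128, median of ratios by -0.043 and upper quartile by 0.068, and list medians moved by the same amounts unless a member crossed the filter. The ratio went with transcript length: over 10088 protein-coding genes Spearman's rho was -0.60 across genes, which are not independent replicates. Of 10 equal bins by length, the shortest, with transcripts of 102 to 1166 nt, had a median log2 ratio of 0.62, and the longest, of 6157 to 27908 nt, had -0.76. After correction for this trend, which was added after the data were seen, 219 of these genes were at least 2-fold higher and 319 lower, against 326 and 813 without it.

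**Figure D2:**
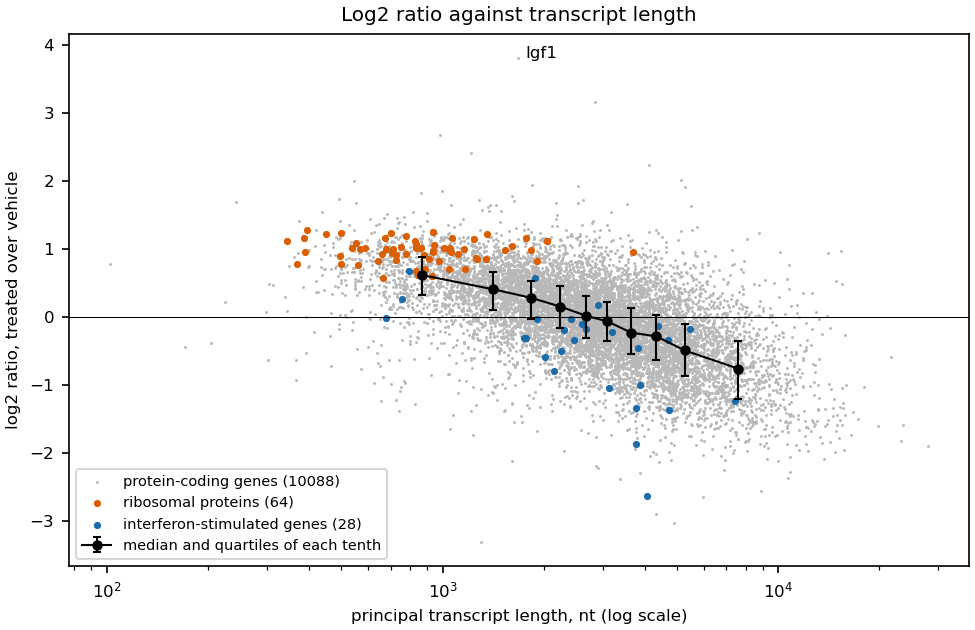
Log2 ratio (treated over vehicle, y axis) against the length of the principal transcript in nt (log x axis) for 10088 protein-coding genes. Black points join the medians of 10 equal bins of genes by length, with quartiles, from 0.62 in the shortest to -0.76 in the longest. The 64 ribosomal protein genes and the 28 interferon-stimulated genes among them are coloured.

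Genes of the IL-4 response were split, with 2 of 8 measured list members higher, both at low counts, and 2 lower. By the same rule, 2097 of all 12264 measured genes were higher and 2429 lower. Besides Cish, Clec10a, a lectin of alternatively activated macrophages, was 2.94-fold higher (1.78 to 5.04) from 61 against 22 counts. Clec7a, the beta-glucan receptor Dectin-1, had a ratio of 1.496 (1.28 to 1.76) and the cytokine gene Tgfb1 one of 1.20 (1.13 to 1.27), both under the 1.5-fold threshold. Stat6, the transcription factor that carries the IL-4 signal, was 1.52-fold lower (1.43 to 1.61), and Kdm6b, a histone demethylase, 2.45-fold lower (1.96 to 3.08). Of the 30 genes fixed as IL-4 response and M2 markers, 18 had a count and 8 were measured. Over the 18, whatever the size of the ratio, 10 intervals lay above 1 and 3 below, or 7 and 2 with counts halved. This tally was not corrected for length. Among the 7 were Clec7a, Tgfb1 and Msr1, the last at a ratio of 1.10 and named after its values were seen. They stood at -0.05, 0.08 and -0.25 in log2 after the length correction. The rest of the 7, Cish, Clec10a, Flt1 and Mgl2, stood at 1.19 or above. Of the 8 measured genes, 2 were at least 1.5-fold higher, 2 at least 1.5-fold lower and 4 lay between, among them Egr2 at 1.34 (0.894 to 2.02). The median log2 ratio of the 8 was 0.34, at percentile 88.2 of 10000 random lists matched on expression, as a description of these libraries. Over the 7 members that could also be matched on length it was 0.26, at percentile 83.8 of such lists. The median of the 8 was 0.02 after the length correction, where Clec7a stood at -0.05, Stat6 at -0.34, no longer 1.5-fold lower, and Kdm6b at -0.66.

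Classical M2 markers were at or near the detection limit. Chil3, Retnla and Il10 had 0 counts in both libraries, and Mrc1, the mannose receptor, had 2 in each. Arg1, the arginase gene induced by IL-4 in macrophages, had 14 counts in the treated and 3 in the vehicle library, a ratio of 4.96 (1.38 to 26.9). The low counts were mostly even numbers, and with counts halved the intervals of Arg1 and of Socs1, Matk and Tgm2 below included 1. The following members were chosen after their values were seen. Mgl2, a lectin paired with Clec10a, had 42 counts against 0 and was at least 14.9-fold higher when set against 3 vehicle counts; its counting interval, which also covers the treated count, started at 11.6-fold, and at 5.53-fold with counts halved. Socs1, a further inhibitor of cytokine signalling, had 6 against 0. Flt1 had 32 against 10 counts and Matk 20 against 8, whereas the receptor gene Il4ra had 32 against 36 and Tgm2, uncertain because 21.8% of its exon length overlaps other genes, had 8 against 26. Clec10a and Mgl2 are close paralogs, so the split of reads between them is uncertain. The 10 members with a count under the filter together had 194 against 115 counts, a ratio of 1.79 (1.42 to 2.28), and without Mgl2 1.40 (1.09 to 1.80), an interval that with counts halved was 0.984 to 2.01 and included 1.

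**Figure D3:**
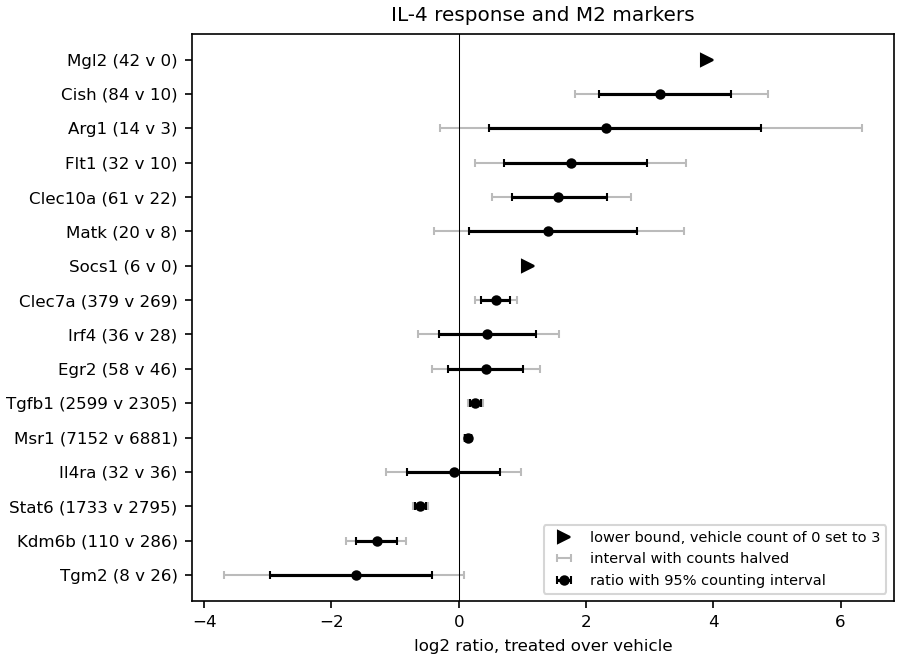
Log2 ratio (treated over vehicle, x axis) of the IL-4 response and M2 markers with more than 3 counts in a library, with treated and vehicle counts in parentheses. Black bars are 95% counting intervals and grey bars the intervals with counts halved. Arrowheads give the treated count set against 3 vehicle counts for genes with 0 vehicle counts. They leave out error in the treated count. Socs1 is drawn at 2.12-fold, but its interval started at 1.25-fold and included 1 with counts halved. Cish stands at 3.16 and Kdm6b at -1.29.

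Inflammatory genes associated with M1 activation differed by gene. Tnf was 2.002-fold lower in the treated library (1.87 to 2.14), at 35.3 against 70.6 CPM. Nos2, the inducible nitric oxide synthase, was 2.26-fold lower (1.57 to 3.30) from 43 against 103 counts, the chemokine gene Cxcl2 2.17-fold (1.67 to 2.85) and Nfkbiz, a nuclear regulator of NF-kappaB, 2.28-fold (1.75 to 2.99). Cd40, Acod1 and Ccl4 went the other way, at ratios of 1.73, 1.56 and 1.52, and Acod1 stood at 0.55 and Ccl4 at -0.05 in log2 after the length correction, below 1.5-fold. Of 14 measured genes, 3 were at least 1.5-fold higher and 5 lower, with a median log2 ratio of -0.14, at percentile 27.1 of random lists matched on expression and percentile 5.49 of lists matched also on transcript length. The median was -0.45 after the length correction, with 1 gene at least 1.5-fold higher and 5 lower, and the pooled value was -0.27. Tnf and Cxcl2 have short transcripts and stood at -1.38 and -1.66 after the length correction. Il1b had 7 against 6 counts, and Il6 had 0 in both libraries.

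Interferon-stimulated genes were lower in the treated library more often than higher. Trim30a, an inhibitor of Toll-like receptor signalling, was 3.64-fold lower (3.30 to 4.02), the guanylate-binding protein gene Gbp7 6.19-fold (3.51 to 11.8) from 14 against 92 counts, the antiviral synthetase gene Oas3 2.58-fold (2.28 to 2.92) and Parp14 2.35-fold (2.20 to 2.52). Trim30a and Gbp7 have near-identical family members, so their values are uncertain. Bst2, the tetherin gene, was higher at a ratio of 1.60 (1.46 to 1.75). Of 30 measured genes, 10 were at least 1.5-fold lower and 1 higher. The median of -0.32 was at percentile 2.36 of lists matched on expression. Over the 28 members that could also be matched on length it was -0.31, at percentile 0.28 of such lists. After the length correction the median was -0.40 over 29 members, of which 13 were at least 1.5-fold lower and 0 higher, with Bst2 at 0.05 and Parp14 at -0.56. Of these 13 genes, 8 were also at least 1.5-fold lower before it.

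Among genes of antigen presentation, 4 of 13 were at least 1.5-fold higher and 9 lay between the thresholds. Beside Cd74, the immunoproteasome genes Psmb8 and Psmb10 were 1.94-fold (1.83 to 2.07) and 1.70-fold (1.49 to 1.93) higher, and the non-classical MHC class I gene H2-T23 1.60-fold (1.45 to 1.78). MHC genes share sequence with one another, so the value of H2-T23 is uncertain. The class II genes H2-Aa and H2-Ab1 and their regulator Ciita had 0 counts in both libraries. After the length correction Cd74 stood at 1.13 in log2, while Psmb8 at 0.58, Psmb10 at 0.28 and H2-T23 at 0.31 were under the 1.5-fold threshold. The list had a median log2 ratio of 0.46 (0.28 after the length correction), at percentile 98.8 of lists matched on expression and percentile 87.2 of lists matched also on length.

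Genes of the cytosolic ribosome and of the respiratory chain were higher as groups. Of 64 ribosomal protein genes, 63 were at least 1.5-fold higher, 28 of them at least 2-fold, and the ratios ran from 1.49 for Rps14, which stood at -0.08 in log2 after the length correction, to 2.43 for Rps21. Rpl8, at 939 against 394 CPM, was 2.39-fold higher (2.34 to 2.43), and Rplp1 and Rps19 were 2.37-fold and 2.35-fold higher. The list's median log2 ratio was 0.99, and it was 0.86 under scaling by total counts and 1.06 under upper-quartile scaling. Ribosomal protein genes have many processed pseudogenes that can share their reads, so single values are uncertain. Of 39 nuclear-encoded oxidative phosphorylation genes, 26 were at least 1.5-fold higher and 0 lower, with a median of 0.75. Ndufs7 of complex I was 2.30-fold higher (2.06 to 2.58) and Cox7b of complex IV 2.19-fold (2.10 to 2.28). Atp5o, at 2.31, shares 43.8% of its exon length with other genes and is uncertain.

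Both groups have short transcripts. Random lists matched on expression and transcript length had median log2 ratios of 0.70 for the ribosomal and 0.56 for the respiratory list, and the lists stood at percentiles 100 and 99.7 of these. After the length correction their medians were 0.37 and 0.24, and 11 of the 63 and 3 of the 26 genes were still at least 1.5-fold higher. Rpl8 then stood at 0.61 in log2, Ndufs7 at 0.55 and Cox7b at 0.49. The 13 genes of the mitochondrial genome were not higher as a group: 3 were at least 1.5-fold higher, led by mt-Atp6 at 1.95 (1.79 to 2.12), while mt-Cytb was 1.44-fold lower (1.41 to 1.46). After the length correction 0 of the 13 were at least 1.5-fold higher and 5 lower. Their median was 0.12, it was -0.01 under scaling by total counts and -0.52 after the length correction, and it lay at percentile 52.3 of lists matched on expression and percentile 0.01 of lists matched also on length. Counts of these genes were very uneven, at 44 and 40 for mt-Co3 beside 65876 and 49327 for mt-Nd5 in the treated and vehicle library. The handling of reads with several matches is not given, so the values of this list are uncertain.

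**Figure D4:**
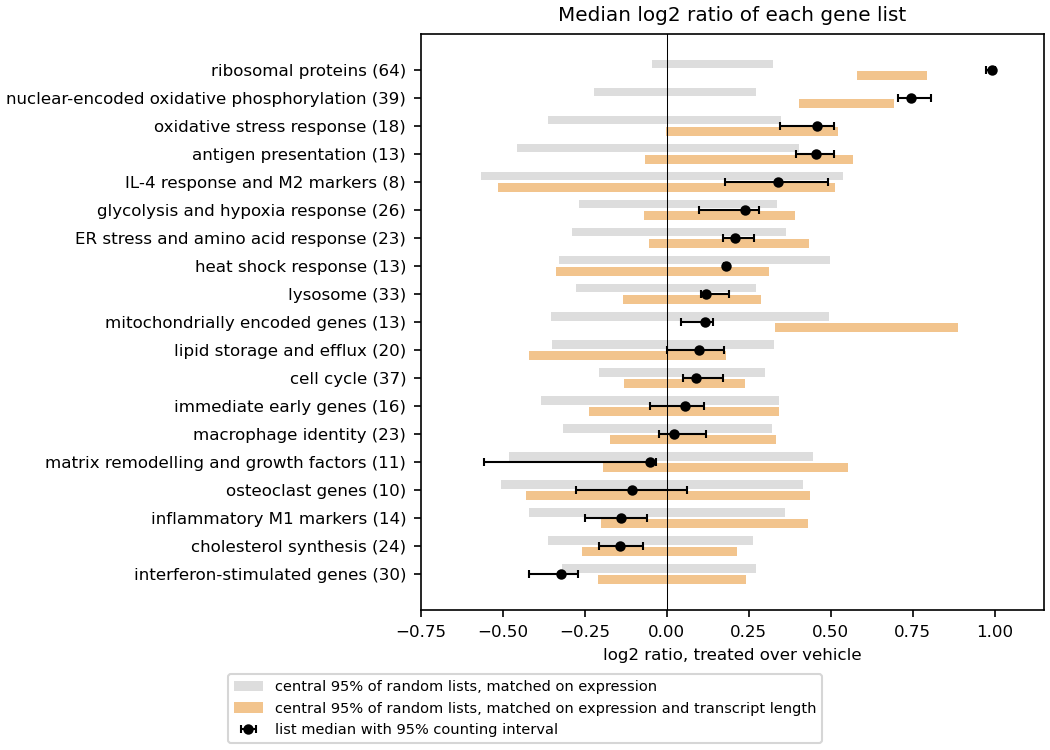
Median log2 ratio (treated over vehicle, x axis) of each gene list with at least 8 measured genes, numbers of genes in parentheses, with 95% counting intervals. Grey and orange bars hold the central 95% of 10000 random lists matched on expression, or on expression and transcript length. The ribosomal proteins at 0.99 lie above both bars and the interferon-stimulated genes at -0.32 below both, while the 8 IL-4 response and M2 markers at 0.34 lie within both. The orange bars of these last lists stand for 28 and 7 members, with medians of -0.31 and 0.26.

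Stress responses were mixed. The antioxidant genes Sod1 and Txn1 were 2.09-fold (2.04 to 2.15) and 1.83-fold (1.66 to 2.01) higher, whereas Hmox1, the heme oxygenase gene, was 1.87-fold lower (1.72 to 2.02). Gpx1 was 1.92-fold higher, but 84.0% of its exon length overlaps other genes. Of 18 oxidative stress genes 7 were at least 1.5-fold higher and 3 lower, with a median log2 ratio of 0.46, at percentile 99.7 of lists matched on expression and percentile 92.7 of lists matched also on length, and of 0.11 after the length correction, where 1 gene was higher and 2 were lower, and Sod1 stood at 0.40, Txn1 at 0.28 and Hmox1 at -1.27. Among 13 heat shock genes 4 were higher, or 3 with counts halved, where the interval of Hspa1a included 1, and 1 was lower, with Hspa1b at 2.66 (2.18 to 3.26, uncertain because of its near-identical copy Hspa1a), Hspa8 at 1.69 (1.68 to 1.71), Hspa4l 1.52-fold lower (1.44 to 1.62; 0.31 in log2 after the length correction) and a median of 0.18 that was 0.01 under scaling by total counts, 0.10 under median of ratios and 0.36 after the length correction. Among 23 ER stress and amino acid response genes 3 were higher and 3 lower, with the transcription factor gene Atf4 at 1.60 (1.55 to 1.66), Sel1l of ER-associated degradation 2.71-fold lower (2.56 to 2.88) and a median of 0.21 that was 0.08 under scaling by total counts and 0.07 after the length correction, where 1 gene was higher and 2 were lower, and Atf4 stood at 0.32. The 1 gene higher after the correction was not higher before it. Of 16 immediate early genes 1 was higher, Klf4 from 76 against 48 counts, and 3 were lower, with Egr1 1.80-fold lower (1.61 to 2.02), a median of 0.06 and a mean of -0.02. With counts halved the interval of Klf4, 0.983 to 2.93, included 1. The median of that list was -0.07 under scaling by total counts and -0.03 after the length correction, where Egr1 stood at -0.58.

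Lipid and sugar metabolism showed no common direction. Hsd17b7, a sterol reductase, was 3.09-fold lower (2.18 to 4.48), whereas Ebp, a sterol isomerase of the same pathway, was 2.18-fold higher (2.04 to 2.33). Of 24 cholesterol synthesis genes 4 were at least 1.5-fold higher and 4 lower, or 2 and 3 after the length correction, with a median log2 ratio of -0.14. The desaturase gene Scd1 was 2.82-fold lower (2.17 to 3.71) and Soat1, which esterifies cholesterol, 1.95-fold lower (1.87 to 2.04). Of 20 lipid storage and efflux genes 1 was higher and 4 lower, or 2 and 2 after the length correction, with a median of 0.10, a mean of -0.05 and a median of -0.03 under scaling by total counts. Fasn, the fatty acid synthase gene, was 1.76-fold lower (1.67 to 1.86) and stood at 0.13 after the length correction, where Soat1 stood at -0.46. Of 26 glycolysis and hypoxia genes 3 were higher and 2 lower, with Pfkl at 1.59 (1.53 to 1.65), Ero1a 1.71-fold lower (1.62 to 1.80) and a median of 0.24 that was 0.11 under scaling by total counts and 0.02 after the length correction, where 1 gene was higher and 3 were lower, none of them lower before it, and Ero1a stood at -0.46.

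Proliferation genes differed by gene. Pcna, the sliding clamp of DNA replication, was higher at a ratio of 1.74 (1.70 to 1.79), with 20.8% of its exon length in other genes and so uncertain, while the centromere protein genes Cenpe and Cenpf, with long transcripts, were 2.002-fold (1.96 to 2.05) and 1.92-fold (1.87 to 1.96) lower and stood at -0.28 and 0.08 after the length correction. Of 37 cell cycle genes 6 were at least 1.5-fold higher and 4 lower, with a median log2 ratio of 0.09, a pooled value of -0.11 and medians of -0.04 under scaling by total counts and 0.05 after the length correction, where 3 genes were higher and 2 lower and Pcna stood at 0.44. Of 3 measured histone genes, H2ac10 was higher at 1.98 (1.36 to 2.92, uncertain because of an overlapping gene), and the median was 0.53, or 0.16 after the length correction, where H2ac10 stood at 0.25. Of 2 measured small structural RNA hosts, Gas5 was at 1.20 (1.17 to 1.24) and Snhg1, which overlaps other genes, at 1.77, with a median of 0.54.

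The list of macrophage identity genes had a median near 0, with single genes apart. Adgre1, which encodes the surface antigen F4/80, was 2.91-fold higher (2.28 to 3.75) and the lineage factor gene Spi1 1.60-fold (1.54 to 1.66). Cybb, the NADPH oxidase subunit, was 1.81-fold lower (1.76 to 1.86). Of 23 macrophage identity genes 3 were at least 1.5-fold higher and 3 lower, with a median log2 ratio of 0.02, a pooled value of -0.10 and medians of -0.11 under scaling by total counts, -0.02 under median of ratios and -0.26 after the length correction, where 2 genes were higher and 5 lower, and Spi1 stood at 0.45 and Cybb at -0.44. Only 1 of these 2 was higher before the correction too, and only 1 of the 5 was lower. Of 33 lysosome genes 5 were higher, including the protease gene Ctsz at 2.10 (2.04 to 2.16), and 5 lower, with a median of 0.12 that was -0.0072 under scaling by total counts. After the length correction 4 of the 33 were higher and 1 lower, and that 1 was not lower before it. Of 10 osteoclast genes 2 were higher and 4 lower, with Mitf 1.99-fold lower (1.83 to 2.16), a median of -0.11, or -0.25 after the length correction, where 1 gene was higher and 0 were lower and Mitf stood at -0.55, and a pooled value of 0.19. Of 11 matrix and growth factor genes 2 were higher, Igf1 and Vegfb, and 5 lower, including the IL-1 receptor antagonist gene Il1rn at 2.13-fold (1.87 to 2.42) and the urokinase receptor gene Plaur at 1.97-fold (1.74 to 2.23). Their median was -0.05, their mean 0.03, and the median was 0.02 under upper-quartile scaling and -0.43 after the length correction, where 1 gene was higher and 5 lower and Vegfb stood at 0.32.

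Fibroblast markers other than Gsn and markers of lymphocytes, neutrophils and endothelium had few or no counts in both libraries, while some adipocyte and muscle markers were measured. Of 22 fibroblast and fibro-adipogenic progenitor markers, only Gsn, which macrophages also express, was measured, at a ratio of 1.28 (1.19 to 1.37). The other 21 together had 26 counts in the treated and 28 in the vehicle library, and Col1a1 and Dcn had 0 in both. None of 18 lymphocyte, neutrophil and endothelial markers was measured, the highest being Pecam1 with 24 against 6 counts. Of 3 measured adipocyte markers 0 were at least 1.5-fold apart, with a median log2 ratio of -0.29, or -0.10 after the length correction. Of 3 measured muscle markers the troponin gene Tnni2 was 1.71-fold higher (1.66 to 1.76), at 314 against 184 CPM, and the median was 0.36. Both the median and Tnni2 were at 0.15 in log2 after the length correction. Genes often used as references were also apart, with Gapdh at 1.55 (1.47 to 1.64), B2m at 1.35 (1.25 to 1.45) and Actb at 1.18 (1.17 to 1.20). After the length correction Gapdh stood at 0.17, Actb at -0.04 and B2m at -0.22. Gapdh, at 84.0 against 54.2 CPM, lay below Tnni2 in both libraries. The handling of reads with several matches is not given, so its value is uncertain.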

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

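Counts halved in the interval and the transcript length correction were chosen after the data were seen, the other settings before. The 514 higher genes became 294 under scaling by total counts (the cause is the shift of all ratios), 1089 without a filter, 210 at 10 CPM, 328 among protein-coding genes, 2097 at 1.5-fold and 175 with whole intervals beyond 2-fold. The 1059 lower genes became 1829, 573, 2429 and 613 without a filter, at 10 CPM, at 1.5-fold and with whole intervals, and were within 1.5 times of 1059 under the other planned settings. Among the 10088 protein-coding genes with a principal transcript, the length correction took 326 higher genes to 219 and 813 lower genes to 319. The IL-4 list median of 0.34 was 0.016 after the length correction, 0.14 at 10 CPM with 3 members, 0.53 as a mean and 0.036 pooled. Without a filter it was 0.44 over 18 members. The M1 list median of -0.14 was -0.27 under total counts, -0.45 after the length correction and -0.27 pooled, but -0.073 under upper quartile. Without a filter it was -0.088 over 26 members. Total counts turned the medians of lipid storage (-0.031), mitochondrially encoded (-0.012), cell cycle (-0.038), lysosome (-0.0072), immediate early (-0.072) and macrophage identity genes (-0.11), median of ratios the last of these (-0.021), and upper quartile that of matrix genes (0.016); 17 of 24 list medians had 1 sign under all 4 scalings. The length correction turned the medians of mitochondrially encoded (-0.52), immediate early (-0.029) and macrophage identity genes (-0.26), and Ccl4 (-0.049), Rps14 (-0.076), Clec7a (-0.050), Msr1 (-0.25), Fasn (0.13), mt-Nd6 (-0.072), Hspa4l (0.31), Cenpf (0.076), Actb (-0.039) and B2m (-0.22). Beyond shifts and gene numbers, the cause was not tested. No named gene whose interval excluded 1 changed sign under another scaling. With halved counts the intervals of Arg1, Klf4, Lipe and Hspa1a, and of the IL-4 list members Socs1, Matk and Tgm2, included 1. Depth limits genes under 1 CPM, where intervals often span several fold, and no setting replaces a second library per group.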

Other observations

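The tests and gene families in this part were chosen after the main results were seen, except the scalings of the ribosomal list, which were planned. Families were taken by symbol among measured protein-coding genes with a principal transcript. Of 78 genes of the mitochondrial ribosome 76 had a ratio above 1, with a median of 1.62-fold and 48 at least 1.5-fold higher. Of 37 proteasome subunits 33 were above 1, with a median of 1.52-fold, and of 23 genes of mitochondrial protein import, such as Timm10 and Tomm7, 22 were above 1, also with a median of 1.52-fold. The medians of these families in log2 were 0.69, 0.60 and 0.60, at percentiles 100, 98.9 and 99.6 of random lists matched on expression and transcript length, whose medians were 0.40, 0.41 and 0.31. The 21 spliceosomal Sm and LSm genes were all above 1, with a median of 1.57-fold, and stood at percentile 85.5 of such lists.

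Zinc finger genes named Zfp, most of which encode DNA-binding repressors, went the other way: 192 of 267 had a ratio below 1, 82 were at least 1.5-fold lower and 9 higher. Their median log2 ratio of -0.31 was at percentile 0.01 of length-matched lists. Among 24 histone lysine methyltransferase and demethylase genes, 22 were below 1 and 12 were at least 1.5-fold lower, with Kmt2a among the lowest and a median of -0.59, at percentile 26.4. Kinesin genes, with a median of -0.42, stood at percentile 38.4. The 9 genes of the interferon-inducible and related GTPases in this set, which does not hold Gvin3, were below 1 under the 4 scalings, with Gbp7, Gvin1 and Gbp9 lowest among them, with a median of -0.53 at percentile 2.98. The 7 genes of the chaperonin CCT in this set were all above 1, with a median of 1.497-fold, at percentile 93.9 of length-matched lists. The 52 translation initiation factor genes, with a median of 0.19, stood at percentile 54.3, and the 20 hnRNP genes, 17 V-ATPase genes and 20 cytosolic aminoacyl-tRNA synthetase genes had medians of 0.11, 0.09 and 0.06, which scaling by total counts, with its shift of -0.128, takes below 0. No other family median changed sign under the 4 scalings. The expression profile was unusual in both libraries. Ncl, which encodes nucleolin, took 3.71% of the treated and 3.91% of the vehicle counts, while mt-Co3 had 44 and 40 counts beside 65876 and 49327 for mt-Nd5. Gapdh stood at only 84.0 and 54.2 CPM.

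Igf1, Cish, Mgl2 and Clec10a, which respond to IL-4 in macrophages and were picked here after their values were seen, were higher in the treated library, although Mgl2 and Clec10a can share reads and the fixed IL-4 list had a median of 0.016 after the length correction. Over 7 of its members, that list stood at percentile 83.8 of lists matched on expression and length. At the lengths of the 4 genes the median trend with transcript length gave a log2 ratio of at most 0.385. This is below the lowest of their counting bounds with counts halved, 0.52. The genes were picked for high values, however, and log2 ratios around the trend had an SD of 0.511. The comparison therefore shows only that they lie above the median trend. RNA of fibroblasts in cell proportions does not account for the Igf1 difference. The 21 markers other than Gsn differed by at most 0.578 CPM at the upper bound, against 45.5 CPM for Igf1. Cish, Mgl2 and Clec10a were not set against this bound, and RNA that vesicles carry selectively was not tested. A weaker response to IL-4 in the vehicle culture stays open: Cish was at 0.265 CPM there, and without a library of cells free of IL-4 this level decides nothing. A stronger IL-4 response under FAPD10-exos is a candidate explanation that was not tested.

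The ratio went with transcript length over most of the transcriptome. GC content does not account for this, since the partial rho given GC was -0.586. Ribosomal, mitoribosomal and respiratory genes alone do not either, since rho without these genes was also -0.586. A difference in library preparation or RNA quality could produce such a trend, and genes that are not protein-coding showed a rho of -0.27 with exon length. With 1 library per group, that explanation and an effect of the treatment cannot be told apart.

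Ribosomal protein genes were higher than their short transcripts predicted. The list stood at percentile 100 of lists matched on expression and length, which had a median of 0.70 against the 0.99 seen. Such lists drew genes independently of one another and matched them in broad bins. The trend was also steeper among 1600 protein-coding genes with at least 100 CPM, with a rho of -0.69. The percentile therefore cannot decide whether the length trend is the whole cause. The choice among the 4 scalings does not account for the higher ribosomal values, since the lowest median under them was 0.86. Their largest shift from the main scaling was -0.128 for all genes, so they cannot exclude a scaling error common to all 4. As a hypothesis, a part of the difference may be specific to these genes, and reads shared with their pseudogenes were not tested.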
